A study of Homo sapiens with 12 samples.

How the data were processed

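K562 cells were grown with or without 0.2 mM palmitate coupled to albumin, for 20 h per the labels and 16 h per the legends inside the tables of experiments 2 and 3. A dose of 0.2 mM palmitoleate is given for the mixture, and none for palmitoleate alone. Total RNA of 3 biological replicates was pooled before library preparation, and stranded poly(A)-selected libraries were sequenced in paired ends on 1 of 2 run modes of the same Illumina instrument type. Which library was run in which mode is not stated. According to the submitters' processing notes, reads were mapped to UCSC hg19 with TopHat2 and multi-read correction, and Cuffdiff then normalised, quantified and compared the libraries in pairs, with versions not stated. The deposited values are FPKM per gene, scaled by the authors with Cuffdiff between the libraries of 1 table, and 1 table was made per experiment. The p-value and q-value columns deposited by the authors come from Cuffdiff tests between 2 single libraries, and were tallied but not used for any call here.

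Each of the 3 tables lists 23284, 23284 and 23262 genes. Left out were 26 symbols that had turned into dates, genes marked as failed or capped (2, 2 and 6) and genes whose listings differed between pairs by a relative difference over 0.01 (2, 0 and 11). That left 23157 genes shared by all 3 tables. The tables hold 2 libraries that are not in the labels, which were not used, and the labelled untreated GPAT4 knockout library has no values under its name. The 10 most abundant genes took 9.2 to 13.3% of a library's summed FPKM, RPS18 ranked first in each library, and 6728 to 7827 genes per library were listed at 0. Read counts being unknown, no counting interval or detection limit was computed, and precision rests on the spread between experiments.

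Values were taken as log2(FPKM + 1), and ratios were formed only between libraries of 1 table. The wild-type response to palmitate is the mean of 3 ratios, 1 per experiment, tested against 0 with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05) on 11075 genes with a mean of at least 1 FPKM, of which 185 are small RNA genes. The alternative without small RNA genes also leaves out the SNAR genes, which are not counted among the 185, and tests 10876 genes. The experiments are thus paired: across genes, an untreated library correlated with the palmitate library of its own experiment at 0.388, 0.694 and 0.725 after the mean over experiments was removed, and with those of the other experiments at -0.586 to 0.079. A comparison of 2 libraries used the same spread (2 residual and 3.86 prior degrees of freedom), on the assumption that the lone libraries vary as the wild-type ratios do between experiments, and a difference of responses was given the variance of 2 ratios. Intervals are 95% limma intervals.

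Gene lists, comparisons, tests, thresholds and alternatives were chosen before the data were examined, except for the comparisons of knockout or knockdown with wild type under palmitate, for the alternatives without small RNA and SNAR genes and with the GC trend removed, and for tests named as later in the closing section. Camera, with its preset correlation between genes, tested 26 lists with at least 5 tested members and called 12 higher and 5 lower. With an estimated correlation it called 0. That form of the test rests on the 2 residual degrees of freedom of the ratios, so it could hardly call any list. The preset form takes its p from the spread across genes, which are not replicates. The metallothionein list had fewer than 5 tested members and was left out. For single libraries the median of a list is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Fixed markers of T cells, B cells, monocytes, fibroblasts, epithelial and endothelial cells were read as FPKM.

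Named genes follow a fixed rule: GPAT4 and RNF213 in every library; in each comparison the 12 largest rises and 12 largest falls among called genes at 5 FPKM or more, without small RNA genes, with remaining places filled by size of the ratio and given as values; the 4 members of a described list with the largest change; and a panel of 22 genes of stress and lipid metabolism. Genes described as present in 1 library of an experiment and absent from the others were named after their values were seen. GPAT4 is AGPAT6 in the files, IL8 is now CXCL8 and NGFRAP1 is now BEX3.

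GC content and length came from the longest transcript of each gene in a GRCh37 annotation, the assembly that hg19 denotes, matched on current or older symbols for 87% of tested genes. A GC trend was removed, where stated, with a lowess curve (window of 0.3 of the genes) of each library's ratio to untreated wild type. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, ratios centred on their median, no replicate block, no intensity trend and leaving out each experiment. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

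The test was checked on simulated ratios with 200 changed genes. For the wild-type response it recovered 0, 2, 50 and 92% of 50 genes each at 1.5, 2, 4 and 8-fold, with 0 unchanged genes called. The only comparison of 2 libraries simulated was both fatty acids against palmitate. There, and for the difference of responses, the test recovered 0% at each of these folds. A lack of calls there thus says little about changes of up to 8-fold. Without small RNA and SNAR genes the shares were 0, 4, 58 and 92% for the wild-type response, and still 0% for the others simulated. The data differ from this setting: with both fatty acids against palmitate, 967 genes were at least 2-fold higher and 1107 lower. Adjusted p is less strict with more changed genes, so the 0% does not carry over to the data or to comparisons not simulated. Simulated noise had each gene's own wild-type spread, so genes at 0 in all 6 wild-type libraries stayed at 0. The 0 unchanged genes called thus say nothing about calls on such genes.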

Results

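Messenger RNA was sequenced from K562 cells, a human leukemia line that expresses erythroid and megakaryocytic genes, after exposure to fatty acids coupled to albumin. Palmitate is a saturated fatty acid, and palmitoleate is the monounsaturated acid of the same chain length. The 12 labelled libraries came from 3 experiments, and each library held RNA pooled from 3 biological replicates, so that every condition had 1 library per experiment. Experiment 1 held wild-type cells that were untreated, given palmitate or given palmitoleate. Experiment 2 held wild-type cells that were untreated, given palmitate or given both fatty acids, and cells with a knockout of GPAT4, a glycerol-3-phosphate acyltransferase that starts glycerolipid synthesis, untreated and given palmitate. Experiment 3 held wild-type cells and cells with a knockdown of RNF213, a large ubiquitin ligase, each untreated and given palmitate. Untreated wild type and wild type with palmitate thus had 3 libraries each, and each of the other 6 groups had 1. The untreated GPAT4 knockout library was not used here, because the table of experiment 2 has no values under its name. That table holds a library that its legend calls a GPAT4 knockout, with no treatment given, under a name that the labels lack, and it was set aside. The 11 libraries used summed to between 612355 and 821188 FPKM and held 10495 to 11108 genes at 1 FPKM or more. Read counts are not part of the files, so the depth behind each value is unknown.

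The response of wild-type cells to palmitate was measured in all 3 experiments, as 3 ratios of palmitate to untreated. IL8, the gene of a neutrophil-attracting chemokine, rose by 7.35 ± 0.61 on the log2 scale (mean ± SE, n = 3 experiments, adjusted p = 0.012), from 2.56 to 257 FPKM in experiment 1, from 0.0843 to 695 FPKM in experiment 2 and from 0.991 to 186 FPKM in experiment 3. ATF3, a stress-induced transcription factor, rose by 4.84 ± 0.48 (adjusted p = 0.0132). DDIT3, which encodes the stress factor CHOP, rose by 3.05 ± 0.27, and HSPA5, the main chaperone of the endoplasmic reticulum (ER), rose by 3.07 ± 0.20 (adjusted p = 0.012 for both). PLIN2, which coats lipid droplets, rose by 2.61 ± 0.24 (adjusted p = 0.0126). KLF1, a transcription factor of red cell development, fell by 2.83 ± 0.48 (adjusted p = 0.0295), from 71.8 to 16.2 FPKM in experiment 1, from 89.8 to 3.54 FPKM in experiment 2 and from 36.2 to 7.82 FPKM in experiment 3.

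Further rises among those at 5 FPKM or more included those of SPRR2D (5.36), INHBE (4.61), OLAH (4.47), IFI16 (4.19), SH3BGR (4.00), CXCL3 (3.94), CDKN1A (3.91) and IL20RB (3.88), each given as the mean log2 ratio. HBBP1 fell by 3.32, FAM178B fell by 2.94, NFE2 fell by 2.78 and HEMGN fell by 2.62. PKLR, the pyruvate kinase gene of red cells and liver, fell by 2.30, and KCNH2 fell by 2.26. FAM213B fell by 2.22, IFI30 fell by 2.19, ARHGAP22 fell by 2.19, NEFH fell by 2.14, and SLC25A10, a mitochondrial dicarboxylate carrier, fell by 2.13. limma called 730 genes higher and 425 lower among 11075 tested, with a smallest adjusted p of 0.00984, and 3610 genes had an unadjusted p under 0.05. All 1155 called genes moved the same way in all 3 experiments, and 613 of the rises and 363 of the falls were at least 2-fold on average. In 2 alternatives chosen after the data were seen rises and falls were nearer in number: limma called 1233 genes higher and 1206 lower with small RNA and SNAR genes left out (10876 tested), and 1332 higher and 1440 lower with a trend on GC content removed (9637 tested). Among the tested genes, 2864 were higher and 3275 lower in all 3 experiments, which is 55.4% where chance gives 25%. With no filter on expression limma called 0 genes (smallest adjusted p = 0.158, 4155 genes at an unadjusted p under 0.05), and without pairing by experiment it called 258 higher and 51 lower. With the libraries of experiment 1 left out, limma called 0 genes (smallest adjusted p = 0.0521, 4474 genes at an unadjusted p under 0.05), and with those of experiment 3 left out it also called 0 (smallest adjusted p = 0.131, 2330 genes). In experiment 1 the palmitate ratio followed the GC content of the transcripts across genes (Spearman's rho = -0.64), against -0.02 in experiment 2 and 0.15 in experiment 3.

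The genes of the integrated stress response, the ATF4 program that supplies amino acids and signals stress, rose together: 22 of 25 tested members rose, 23 when adjusted over the list alone, with a median log2 ratio of 2.04. GDF15, a circulating stress signal, rose by 3.87 ± 0.33, NUPR1 by 3.44, DDIT4 by 3.27 and the pseudokinase gene TRIB3 by 2.72. ATF4 itself rose by 1.30 ± 0.29, CHAC1 by 2.04 and ASNS, asparagine synthetase, by 2.55 ± 0.20. Camera gave the list an adjusted p of 6.15e-16, and an adjusted p = 0.42 with an estimated correlation. Of 10 amino acid transporters, 4 rose (7 when adjusted over the list alone), among them the cystine carrier SLC7A11 by 3.06 and its partner SLC3A2 by 2.37 (camera adjusted p = 2.45e-05, and adjusted p = 0.42 with an estimated correlation). The list medians of both groups were above 0 in each experiment, at 1.53, 2.77 and 2.39 for the stress response genes and at 0.40, 1.09 and 1.28 for the transporters.

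Protein folding genes of the ER rose as well. Of 21 ER chaperones and folding enzymes, 15 rose and 0 fell (19 and 0 when adjusted over the list alone), with DNAJB9 at 3.12 ± 0.24, MANF at 2.35, ERO1LB at 1.97 and SDF2L1 at 1.27. Of 32 genes of ER-associated degradation and the secretory pathway, 20 rose and 0 fell (29 and 0 when adjusted over the list alone), led by HERPUD1 at 3.21 ± 0.25, SEC24D at 2.77 and EDEM1 at 2.52. XBP1, the transcription factor that drives many of these genes, rose by 1.33 ± 0.23 (adjusted p = 0.0297). Camera gave adjusted p values of 2.75e-13 and 1.78e-16 for these lists, and an adjusted p = 0.42 with an estimated correlation for each.

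Oxidative stress and inflammatory genes were a further group of rises. Of 16 NRF2 targets, 12 rose (14 when adjusted over the list alone), including OSGIN1 by 3.84 ± 0.31 and GCLC, which limits glutathione synthesis, by 2.00. Of 12 NF-kappaB and inflammatory genes, 9 rose (10 when adjusted over the list alone), with IER3 at 3.12 and CXCL2 at 3.06 beside IL8 and CXCL3. Camera gave adjusted p values of 9.37e-10 and 1.12e-08, and an adjusted p = 0.42 with an estimated correlation for each. Of 13 immediate early genes, 5 rose (10 when adjusted over the list alone), among them KLF6 by 4.03 and JUN by 2.97, whereas EGR1 at 2.39 (adjusted p = 0.0751) and NR4A1 at 2.22 (adjusted p = 0.0517) did not pass. That list had a camera adjusted p of 1.28e-06, and an adjusted p = 0.427 with an estimated correlation.

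Genes of cell death and of lysosomes moved in part. Of 15 apoptosis regulators, 5 rose and 1 fell (6 and 1 when adjusted over the list alone). The death receptor gene TNFRSF10B rose by 2.97, the BH3-only genes BBC3 and PMAIP1 rose by 2.37 and 2.27, and MCL1, which protects from apoptosis, rose by 1.24. Of 12 p53 targets, 3 rose (4 when adjusted over the list alone), with CDKN1A at 3.91 and GADD45A at 1.56. Of 24 lysosome and autophagy genes, 10 rose (12 higher and 1 lower when adjusted over the list alone), with WIPI1 at 3.23, SQSTM1 at 2.97 ± 0.20, CTSL1 at 2.89 and GABARAPL1 at 2.30. Camera gave adjusted p values of 0.0249, 0.0406 and 1.63e-05 for the 3 lists, and an adjusted p = 0.426, 0.427 and 0.426 in turn with an estimated correlation.

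Erythroid and DNA replication genes were lower with palmitate. Of 23 erythroid genes, 10 fell and 0 rose (18 and 0 when adjusted over the list alone), with KLF1, HEMGN and AHSP, the chaperone of alpha globin, which fell by 2.04 ± 0.33. The delta globin gene HBD was at -2.31 (adjusted p = 0.0503). Of 24 DNA replication and G1/S genes, 7 fell and 0 rose (19 and 0 when adjusted over the list alone), and UNG fell by 1.82, CCNE1 fell by 1.57 and MCM2 fell by 1.33. Camera gave adjusted p values of 4.4e-07 and 5.94e-07, and an adjusted p = 0.426 with an estimated correlation for each list. The median of the erythroid list was -0.82, -1.88 and -0.93 in experiments 1 to 3.

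Of 24 genes of cholesterol synthesis and uptake, 4 rose (8 when adjusted over the list alone), STARD4 by 1.89, HSD17B7 by 1.56, MSMO1 by 1.38 and CYP51A1 by 1.08, while HMGCS1 at 1.05 (adjusted p = 0.0615) and INSIG1 at 0.70 did not pass. The list had a camera adjusted p of 4.4e-04, and an adjusted p = 0.42 with an estimated correlation. Of 15 genes of fatty acid synthesis and desaturation, 1 rose, ME1, which makes NADPH (1.77), with SCD at 0.46, FASN at -0.67 (-0.35 with the GC trend removed) and SREBF1 at -0.91 (adjusted p = 0.144, 0.23 and 0.104), and camera gave an adjusted p of 0.9. CPT1A, which admits fatty acids to mitochondria, was at -0.12 ± 0.27 (adjusted p = 0.789). With the GC trend removed in every experiment, the list medians were 2.26 for the integrated stress response, 1.39 for ER chaperones, 0.65 for cholesterol synthesis and -1.13 for erythroid genes, against 2.04, 1.29, 0.54 and -1.20 with it.

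**Figure D1:**
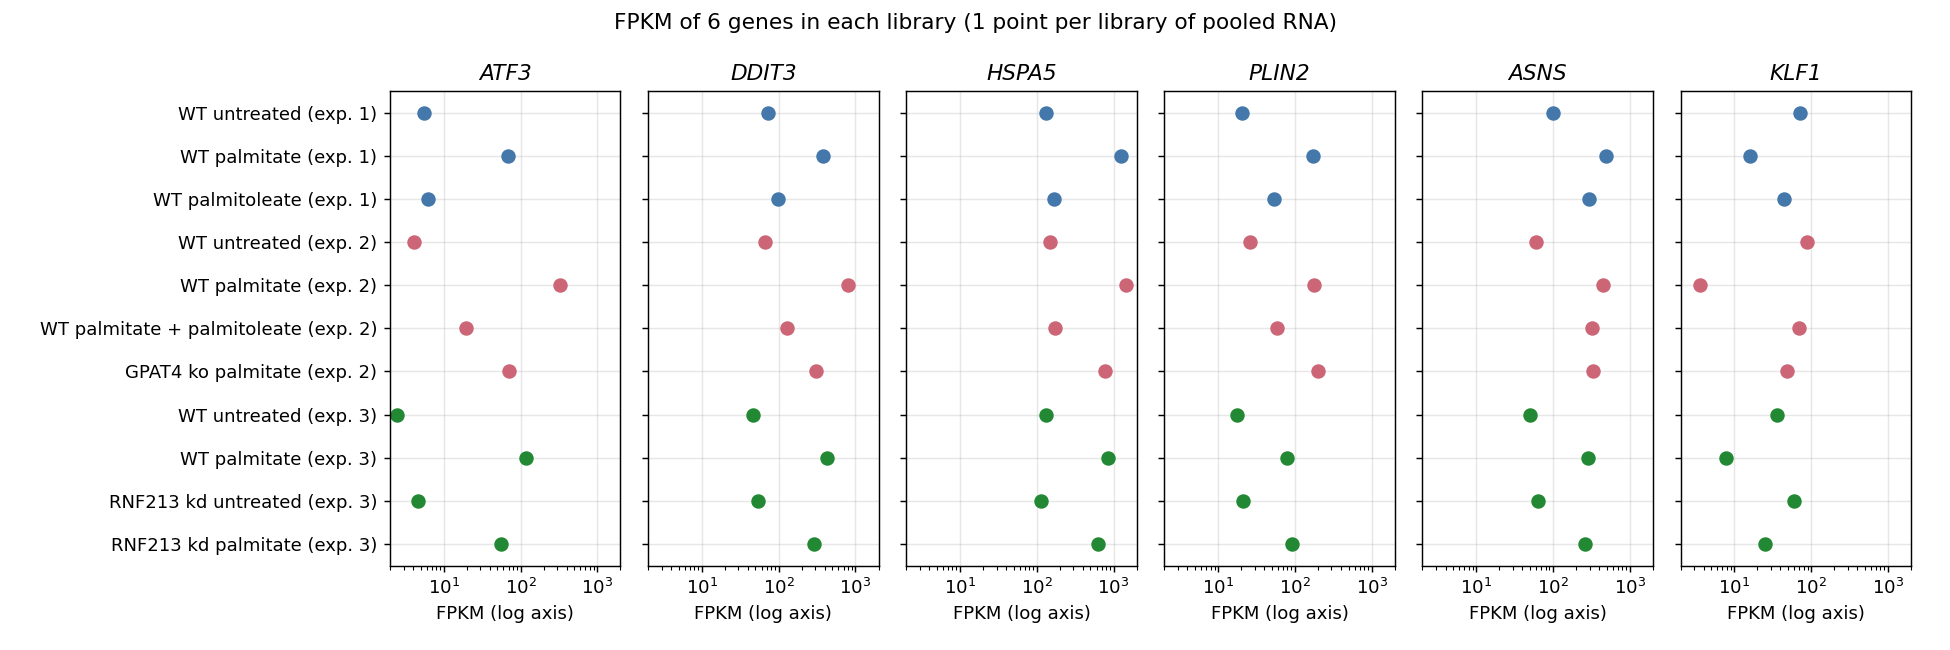
FPKM (log axis) of ATF3, DDIT3, HSPA5, PLIN2, ASNS and KLF1 in the 11 libraries, 1 point per library, coloured by experiment. With palmitate in wild type, ATF3 stood at 67.8, 326 and 118 FPKM in experiments 1 to 3, against 5.47, 4.07 and 2.50 FPKM untreated.

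Whether palmitoleate gives the response that palmitate gives was asked in experiment 1, with 1 library of each, and without replicates. No dose is given for palmitoleate alone, so doses could not be matched. With palmitoleate, genes of ER stress lay closer to their untreated level than to their palmitate level: HSPA5 stood at 132 FPKM untreated, 1259 with palmitate and 170 with palmitoleate, DDIT3 at 72.1, 384 and 99.5, and ATF3 at 5.47, 67.8 and 6.32. Against untreated, HSPA5 had a log2 ratio of 0.36 with a 95% interval of -0.51 to 1.24, and DDIT3 one of 0.46 with an interval of -0.68 to 1.60. Of the integrated stress response genes, ASNS stood at 99.3, 489 and 292 FPKM, a log2 ratio of palmitoleate to untreated of 1.55 ± 0.35, and PSAT1 at 1.10. The lipid droplet gene PLIN2 stood at 20.5, 173 and 52.8 FPKM (1.32 ± 0.42 against untreated). FASN, the fatty acid synthase, stood at 67.7, 21.5 and 18.3 FPKM, and MVD, an enzyme of the mevalonate pathway, at a log2 ratio of -2.09 to untreated. With the GC trend removed the ratios to untreated were -1.03 for FASN (from -1.83), -1.32 for MVD and 0.17 for HSPA5. None of these ratios passed the test (adjusted p = 0.8 or more), which assumes that a lone library varies as wild type does between experiments. The difference between 2 libraries has no replicate check, and a call concerns those libraries rather than the conditions.

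Set against palmitate directly, palmitoleate gave lower values for most of the palmitate-raised genes. The log2 ratio of palmitoleate to palmitate was -6.53 for IL8 (95% interval -9.13 to -3.93), -3.30 for SQSTM1 (-4.17 to -2.44), -2.88 for HSPA5 (-3.75 to -2.01), -2.46 for DNAJB9 (-3.49 to -1.44) and -1.94 for DDIT3 (-3.07 to -0.80), with adjusted p values of 0.458, 0.105, 0.195, 0.46 and 0.57. Panel genes whose interval held 0 included CHAC1 at 0.03 (-1.88 to 1.94), FASN at -0.22 (-1.67 to 1.23), SREBF1 at -0.18 (-1.47 to 1.11), ASNS at -0.74 (-1.59 to 0.12), ATF4 at -0.55 (-1.78 to 0.67), XBP1 at -0.70 (-1.66 to 0.26) and CPT1A at 0.43 (-0.71 to 1.57). These intervals are too wide to show that both fatty acids act alike on those genes. The erythroid genes HBBP1, AHSP and HEMGN stood at 2.22, 1.73 and 1.72 (adjusted p = 0.88, 0.827 and 1). limma called 6 genes higher and 3 lower of 11075 both against untreated (268 genes at an unadjusted p under 0.05) and against palmitate (558 genes), and in each comparison 8 of the 9 were small RNA genes and the other was the non-coding SNAR-H, listed at 85.0, 45.4 and 0 FPKM untreated, with palmitate and with palmitoleate. With small RNA and SNAR genes left out, SNAR-H among them, 11 genes were called against palmitate, including IL8, CXCL3 and SQSTM1 (adjusted p = 0.00778 for each) and HSPA5 (adjusted p = 0.0133), and 0 against untreated (718 genes at an unadjusted p under 0.05).

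As groups, the integrated stress response genes had a median log2 ratio of palmitoleate to untreated of 0.46, above all of 10000 random lists matched on expression, and 20 of 25 members were higher. The ER chaperones had a median of -0.06 (percentile 6.4 of the random lists), fatty acid synthesis and desaturation -0.70 (percentile 0.02), cholesterol synthesis and uptake -0.31 (percentile 0.59), and amino acid transporters 0.02 (percentile 42.53). The palmitoleate ratio to untreated followed GC content across genes (rho = -0.77). With that trend removed the medians were 0.64 for the stress response genes (above all random lists), 0.06 for the ER chaperones (percentile 34.51), -0.57 for fatty acid synthesis and -0.43 for cholesterol synthesis (both below all of them) and 0.36 for the transporters (percentile 99.8). Against palmitate, where rho was 0.13, the list medians were -0.93 for the stress response genes, -1.28 for ER chaperones, -1.82 for NF-kappaB genes and -1.04 for ER-associated degradation, below all 10000 random lists, and 0.86 for erythroid genes, above all of them.

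Palmitoleate was also given together with palmitate, in experiment 2 at 0.2 mM of each, again with 1 library. In that library the ER chaperone HSPA5 stood at 173 FPKM, against 148 untreated and 1451 with palmitate alone, and IL8 at 0.581 FPKM against 0.0843 and 695. KLF1 stood at 70.1 FPKM against 89.8 and 3.54. Several genes of the integrated stress response stood far above untreated: ASNS stood at 318 FPKM against 60.7 untreated and 447 with palmitate, PHGDH, which starts serine synthesis, at 70.6 against 7.29 and 90.6, and DDIT4 at 399 against 20.4 and 463. CHAC1, a glutathione-degrading enzyme, stood at 21.6 FPKM against 0.362 and 8.82. Relative to untreated, the log2 ratio was 4.23 ± 0.83 for DDIT4, 4.06 ± 0.78 for CHAC1, 3.11 ± 0.58 for PHGDH, 2.37 ± 0.35 for ASNS, 1.42 ± 0.44 for HERPUD1 and 0.22 ± 0.35 for HSPA5 (adjusted p = 0.662 for ASNS and 1 for the others).

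Relative to palmitate alone, the log2 ratio with both fatty acids was -8.78 ± 1.06 for IL8, -5.31 for IFI16, -4.93 for KLF6, -3.99 ± 0.84 for ATF3, -3.06 ± 0.35 for HSPA5 and -2.64 ± 0.46 for DDIT3, while KLF1 stood at 3.97 ± 0.82, NFE2 at 3.96 and MYB at 3.21. Adjusted p was 0.147 for IL8 and HSPA5, 0.176 for ATF3 and 0.175 for KLF1. ASNS differed by -0.49 ± 0.35 and CHAC1 by 1.20 ± 0.78. limma called 3 genes higher and 2 lower against untreated (136 genes at an unadjusted p under 0.05) and 3 higher and 2 lower against palmitate (1967 genes), all of them small RNA genes. Without small RNA and SNAR genes, 199 genes were called higher and 416 lower against palmitate, with IL8 at an adjusted p of 0.000878, HSPA5 at 0.00311 and KLF1 at 0.00769, and 0 against untreated (146 genes at an unadjusted p under 0.05). All 25 integrated stress response members were higher than untreated, 16 of them at least 2-fold, with a median of 1.35 above all 10000 random lists, and the median for amino acid transporters was 0.94. The medians against untreated were 0.02 for ER chaperones (percentile 98.98), 0.07 for ER-associated degradation (percentile 99.7), -0.12 for NRF2 targets (percentile 39.59) and 0.33 for NF-kappaB genes (percentile 99.91). Against palmitate they were -1.59 for ER chaperones, -1.97 for NRF2 targets, -2.42 for NF-kappaB genes and -2.86 for immediate early genes, below all 10000 random lists, and 1.36 for erythroid genes, above all of them.

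**Figure D2:**
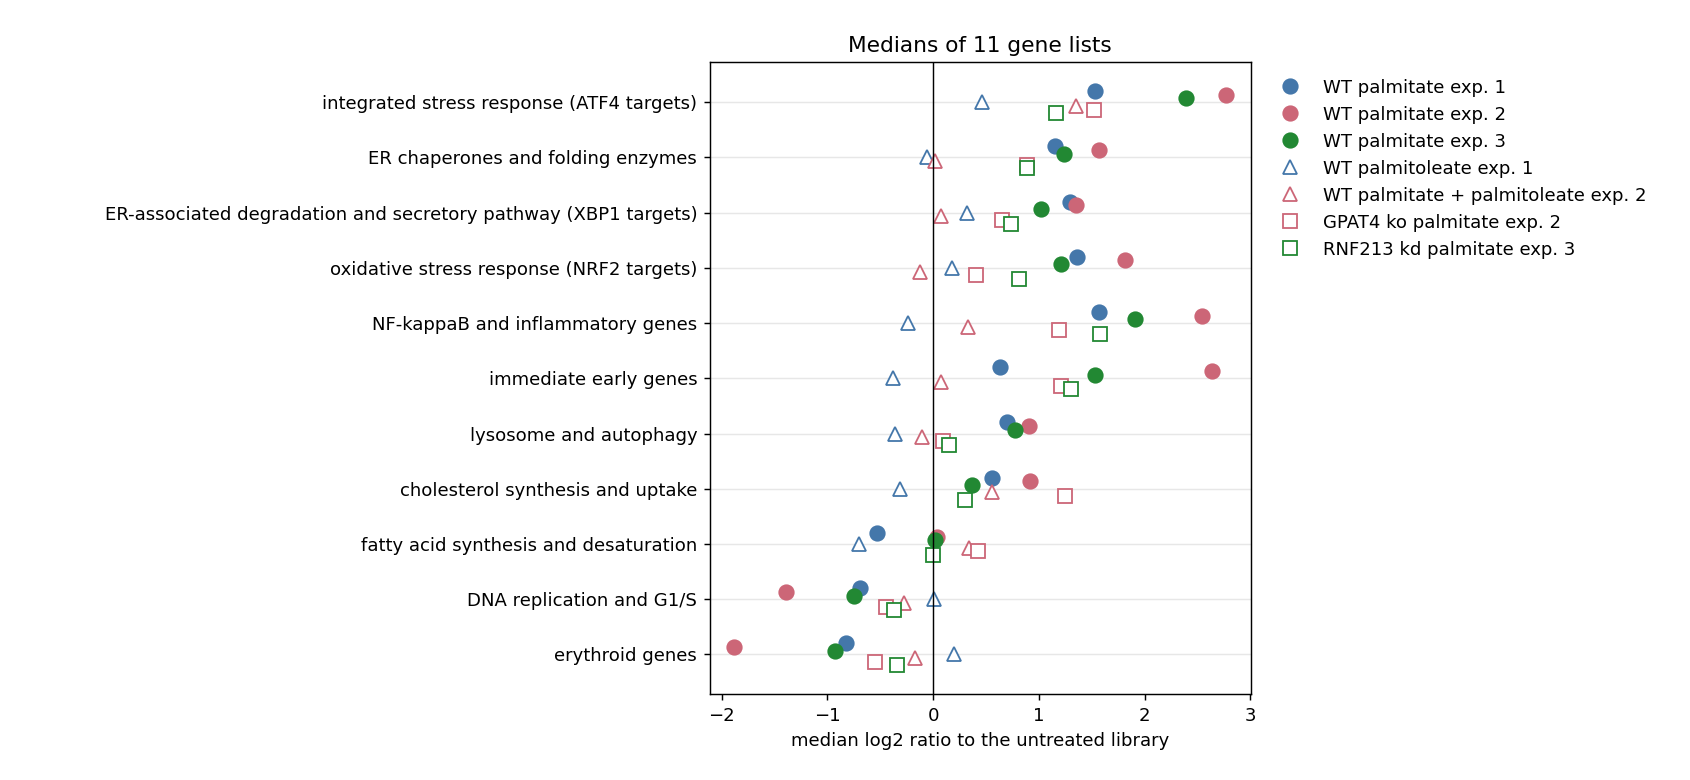
Median log2 ratio to the untreated library of the same experiment for 11 gene lists, 1 point per arm, where the GPAT4 knockout is set against untreated wild type. The median of the integrated stress response was 1.35 with both fatty acids, whereas that of the ER chaperones was 0.02.

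The cells labelled GPAT4 knockout were compared with wild type under palmitate in experiment 2. GPAT4, named AGPAT6 in the files (chromosome 8, 41435707 to 41482520, hg19), stood at 8.77 FPKM in the knockout with palmitate, against 20.0 in wild type with palmitate, 21.0 untreated and 18.0 with both fatty acids in the same experiment, a log2 ratio of knockout to wild type of -1.10 ± 0.33 (adjusted p = 0.34), so that the transcript values alone do not establish the knockout. In experiment 1 it stood at 13.6, 11.8 and 12.5 FPKM untreated, with palmitate and with palmitoleate, and in experiment 3 between 11.8 and 14.1 FPKM. With palmitate, IL8 was at 12.9 FPKM in the knockout and 695 in wild type, ATF3 at 70.3 and 326, DDIT3 at 308 and 800, and KLF1 at 48.4 and 3.54. HSPA5 stood at 784 and 1451 FPKM, ASNS at 331 and 447, and PLIN2 at 199 and 175.

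The log2 ratio of knockout to wild type under palmitate was -5.65 ± 1.06 for IL8, -4.46 ± 0.63 for G0S2, an inhibitor of triglyceride lipase, -2.32 ± 0.32 for AGPAT4, -2.20 ± 0.84 for ATF3, -1.37 ± 0.46 for DDIT3 and -0.89 ± 0.35 for HSPA5. It was 3.81 ± 0.40 for IGFBP4, 3.44 ± 0.82 for KLF1, 1.66 for the desaturase FADS1 and 0.99 ± 0.32 for SCD. limma called 8 genes higher and 0 lower (1434 genes at an unadjusted p under 0.05): 5 small RNA genes and NGFRAP1, MAGEB16 and COL14A1, at 39.9, 21.7 and 10.8 FPKM in the knockout and at or under 0.231 FPKM in each wild-type library of the experiment (adjusted p = 0.0021, 0.00662 and 0.0261). Without small RNA and SNAR genes 90 genes were called higher and 151 lower, with IGFBP4 at an adjusted p of 0.00149, G0S2 at 0.00238, IL8 at 0.0044 and KLF1 at 0.0192. The spread behind the calls of NGFRAP1, MAGEB16 and COL14A1 comes from wild-type libraries, which held them at or under 0.231 FPKM in experiment 2. It therefore does not measure how these 3 genes vary at the level of the knockout. SPARC, KYNU and ARHGAP15, at 10.7, 9.51 and 8.10 FPKM in the knockout, were at or under 0.31 FPKM in the wild-type libraries of experiment 2 but between 4.08 and 13.2 FPKM in those of experiments 1 and 3. The wild type of experiment 2 thus differs from the others in these genes, and the ratios and calls of knockout against wild type cannot be assigned to GPAT4 alone. Without experiment 1 in the spread, 0 genes were called (2413 at an unadjusted p under 0.05).

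By list, the knockout under palmitate was lower than wild type under palmitate for the integrated stress response (median -0.71), ER chaperones (-0.49), NRF2 targets (-1.16), NF-kappaB genes (-1.65) and lysosome and autophagy genes (-0.93), below all 10000 random lists, and higher for erythroid genes (1.23), DNA replication (0.77) and fatty acid synthesis (0.88), above all of them. Against untreated wild type, the knockout with palmitate had medians of 1.52 for the integrated stress response, 0.89 for ER chaperones, 1.19 for NF-kappaB genes (above all 10000 random lists) and -0.55 for erythroid genes (below all of them), where wild type with palmitate had 2.77, 1.57, 2.54 and -1.88. Cholesterol synthesis stood at 1.25 against 0.92, and fatty acid synthesis at 0.42 against 0.04. In experiments 1 and 3, wild type with palmitate had 1.53 and 2.39 for the integrated stress response and 1.15 and 1.24 for ER chaperones. It had 1.57 and 1.91 for NF-kappaB genes and -0.82 and -0.93 for erythroid genes. In these lists wild type of experiments 1 and 3 thus lay nearer to the knockout than wild type of experiment 2 did. Because untreated knockout values were not used here, the palmitate response of the knockout and its difference from that of wild type were not tested.

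The RNF213 knockdown was compared with wild type in experiment 3, untreated and with palmitate. RNF213 (chromosome 17, 78234660 to 78411884, hg19) stood at 1.96 FPKM in untreated wild type and 1.39 in the untreated knockdown, and at 3.08 and 1.54 FPKM with palmitate, for log2 ratios of -0.31 ± 0.41 and -0.68 ± 0.41 (adjusted p = 1 for both), which do not establish the knockdown named by the labels. In the other experiments it stood at 4.67, 6.26 and 3.98 FPKM untreated, with palmitate and with palmitoleate, and at 1.49, 4.76, 2.52 and 2.42 FPKM untreated, with palmitate, with both fatty acids and in the GPAT4 knockout with palmitate. From untreated to palmitate in the knockdown, HSPA5 went from 115 to 619 FPKM (from 132 to 855 in wild type), DDIT3 from 53.9 to 289 (46.2 to 426), ATF3 from 4.60 to 56.3 (2.50 to 118) and IL8 from 0.955 to 155 (0.991 to 186). PLIN2 went from 20.8 to 91.8 FPKM (17.7 to 79.5) and ASNS from 64.6 to 264 (49.6 to 283).

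The palmitate ratio in the knockdown was 6.32 ± 1.06 for IL8, 3.36 ± 0.84 for ATF3, 2.41 ± 0.35 for HSPA5, 2.40 ± 0.46 for DDIT3 and 2.09 ± 0.42 for PLIN2 (adjusted p = 0.298, 0.926, 0.198, 0.462 and 0.531, none of which passed), and CXCL3, a chemokine gene, was called at 4.12 ± 0.38 (adjusted p = 0.0253). limma called 11 genes higher and 10 lower (302 genes at an unadjusted p under 0.05), 19 of them small RNA genes beside CXCL3 and SNAR-H. Without small RNA and SNAR genes 8 genes were called higher and 0 lower (332 at an unadjusted p under 0.05), among them CXCL3 (adjusted p = 0.00326), IL8 (0.0165), OSGIN1 (0.048) and HSPA5 (0.0487). The list medians were 1.16 for the integrated stress response, 0.89 for ER chaperones and 1.58 for NF-kappaB genes, above all 10000 random lists, and -0.34 for erythroid genes, below all of them, though -0.16 with the GC trend removed (percentile 3.99). Between knockdown and wild type, untreated, limma called 12 genes higher and 3 lower (65 genes at an unadjusted p under 0.05), all small RNA genes, and DDIT4, an mTOR inhibitor, stood at 98.4 against 20.9 FPKM (log2 ratio 2.19 ± 0.83, adjusted p = 1). That ratio followed GC content across genes (rho = 0.65), and the median of the integrated stress response was 0.34, or 0.18 with the trend removed (percentile 99.95).

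With palmitate in both, the embryonic and alpha globin genes were higher in the knockdown, HBZ at 541 against 145 FPKM (1.89 ± 0.62), HBA2 at 613 against 178 (1.78 ± 0.66) and HBA1 at 696 against 208 (1.74 ± 0.50), and G0S2 was lower at 7.89 against 25.3 (-1.56 ± 0.63), with an adjusted p = 1 for each. HBZ varied from 304 to 2260 FPKM between the untreated wild-type libraries. Without palmitate HBZ already stood higher in the knockdown than in wild type, at a log2 ratio of 1.11 (0.83 with the GC trend removed), which did not pass. The erythroid list had a median of 0.18 in that untreated comparison (percentile 98.68). limma called 8 genes higher and 3 lower (88 genes at an unadjusted p under 0.05), 10 small RNA genes and SNAR-H. List medians of knockdown to wild type were -0.33 for the integrated stress response, -0.40 for ER chaperones and -0.41 for NRF2 targets, below all 10000 random lists, and 0.81 for erythroid genes, above all of them. The difference of the palmitate responses itself, knockdown minus wild type, was -1.73 ± 1.18 for ATF3, -0.77 ± 0.65 for DDIT3, -0.27 ± 0.50 for HSPA5, -0.02 ± 0.59 for PLIN2 and 1.69 ± 1.07 for HEMGN, none of which passed (adjusted p = 1). limma called 8 genes with a higher and 10 with a lower response, all small RNA genes (61 genes at an unadjusted p under 0.05). By list, that difference had a median of -0.74 for the integrated stress response, -0.55 for NRF2 targets and -0.50 for lysosome and autophagy genes, below all 10000 random lists, and 0.47 for heat shock proteins and 0.63 for erythroid genes, above all of them (0.36, at percentile 99.91, and 0.71 with the GC trend removed).

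The arms were set side by side on genes that palmitate moved at least 2-fold the same way in wild type of the other 2 experiments, so that no library both chose the genes and was measured. In experiment 1, 637 raised genes had a median log2 ratio to untreated of 1.20 with palmitate and -0.04 with palmitoleate (quartiles -0.39 and 0.31), and 208 lowered genes had -0.82 and 0.06. In experiment 2, 369 raised genes, IL8, ATF3 and HSPA5 among them, had a median of 2.30 with palmitate, 0.32 with both fatty acids and 1.00 in the GPAT4 knockout with palmitate, and 89 lowered genes had -2.20, -0.25 and -0.57. Of these, 355 of the 369 and 87 of the 89 were closer to untreated wild type in the knockout than in wild type with palmitate. In experiment 3, 524 raised genes had a median of 1.32 in wild type and 0.91 in the RNF213 knockdown against its own untreated library, and 472 lowered genes had -0.66 and -0.55. Of these, 479 of the 524 and 295 of the 472 were closer to 0 in the knockdown. Without palmitate the 472 lowered genes already stood higher in the knockdown than in wild type (median 0.26, 419 higher and 48 lower). The 2 ratios of the lowered genes thus start from different measured levels, while the 524 raised genes stood at -0.03 untreated. That untreated comparison followed GC content across genes (rho = 0.65), and the 0.26 is given with this trend in place. The palmitate ratio of experiment 1, used to choose these genes, also followed GC content (rho = -0.64). Genes are not independent replicates, and each arm rests on 1 library.

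**Figure D3:**
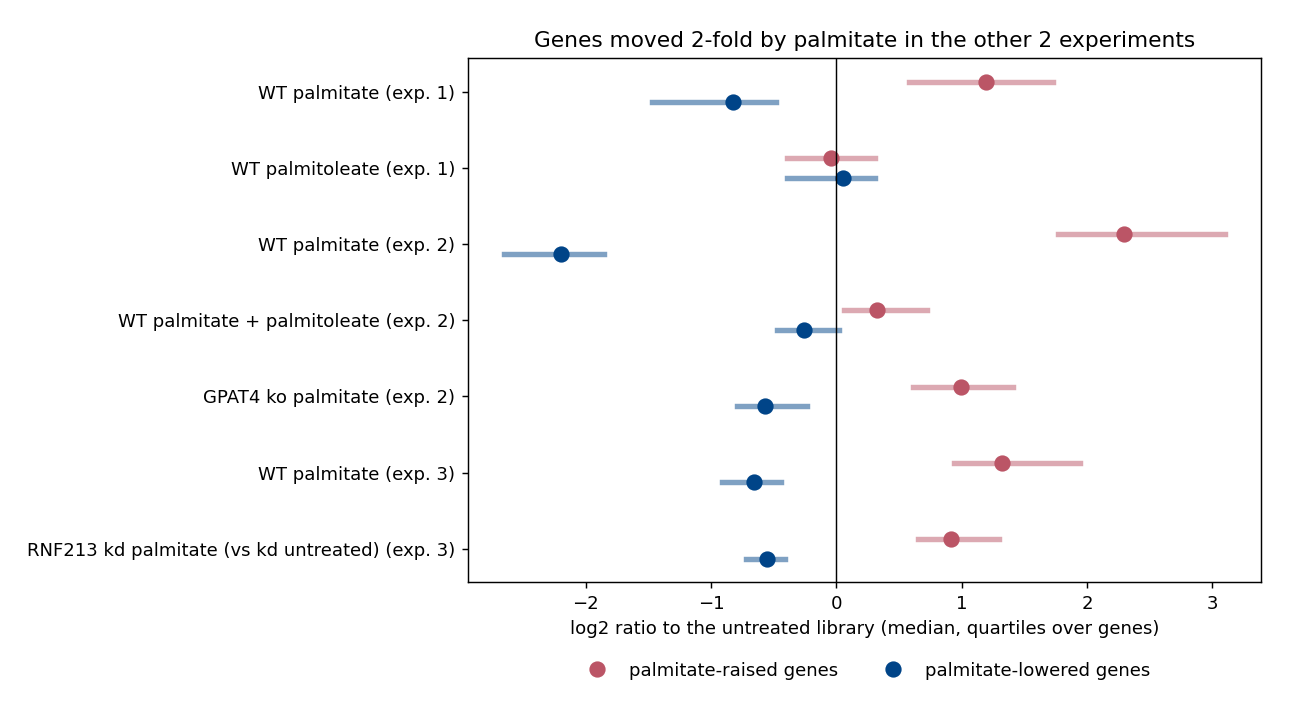
Median log2 ratio to the untreated library (points, with bars for the quartiles over genes) of genes raised or lowered at least 2-fold by palmitate in wild type of the other 2 experiments. Wild type with palmitate stood at 2.30 for raised genes in experiment 2, the GPAT4 knockout with palmitate at 1.00 and wild type with both fatty acids at 0.32.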

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

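Of the tests in this part, the share of called small RNA genes listed at 0, the count of genes at 0 with palmitate and the spread between untreated libraries were chosen after the result was seen, as were the alternatives without small RNA and SNAR genes and with the GC trend removed.

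In limma's test of the difference itself the palmitate response in the RNF213 knockdown, with 1 pair of libraries, was called higher than in wild type for 8 genes and lower for 10, all small RNA genes. The pattern is wider, since 75 calls in the comparisons of 2 libraries fell on 39 small RNA genes, and as 27 of the 39 were at 0 in all 6 wild-type libraries that give the spread, such calls do not establish a difference. A change in small RNA with the knockdown stays open: of 15 such genes called between the untreated knockdown and wild type, 5 (33.3%) went the same way with palmitate, but the bound of 50% set for that share was wrong, since 10 were listed at 0 in both libraries with palmitate and show no direction. Values of exactly 0 stay open as a candidate explanation as well, since 100% of the called instances were listed at 0 in a compared library, against 51% of small RNA genes not called, and the median SD of their wild-type ratios was 0 against 0.362 for all tested genes. Without small RNA and SNAR genes 0 genes were called by limma in that test (16 at an unadjusted p under 0.05), and reads shared between near-identical copies were not tested.

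With palmitoleate in experiment 1, 723 genes were at least 2-fold lower than untreated and 31 at least 2-fold higher. A response common to both fatty acids and to all 3 experiments is argued against, since these genes had medians of -0.19 and 0.07 with palmitate in experiments 2 and 3 against -1.31 in experiment 1, further apart than any untreated library lay from the mean of the other 2 experiments. The -1.31 shares its untreated library with the choice of these genes, and palmitoleate alone was given in experiment 1 only. An untreated library that stands apart stays open: over the lowered genes it lay 0.21 (log2) above those of experiments 2 and 3, but the bound of 0.25 was wrong, since these 2 lay at 0.43 and -0.62 against the other experiments, and the palmitate libraries of experiment 1 and the others differed by -1.06. GC content stays open as well: the ratio followed it across genes (rho = -0.77, against 0.06 for transcript length), the lowered genes held 60.7% GC at the median against 47.6% for tested genes, and removing a joint trend on GC content and transcript length left 58 of 663 matched genes 2-fold lower. A technical difference between the untreated and the 2 fatty acid libraries of experiment 1 may therefore underlie the excess of falls, but an effect of both acids on GC-rich transcripts in that experiment was not tested, and no biological group in the design separates them.

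For the wild-type response to palmitate, the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 1155 genes, the highest of the others called 11, and 1 of the 10 splits reached the real count. The 3 other splits that part all 3 experiment pairs called 0 genes each, and the 6 splits that part 1 pair called 0 to 11.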

How the results depend on the processing

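The alternatives without small RNA genes (SNAR genes also left out) and with the GC trend removed were chosen after the data were seen, as were all alternatives for knockout or knockdown against wild type under palmitate, and the others before. In the wild-type response to palmitate, 0 of the 1155 called genes reversed among those tested (847 at 5 FPKM, 1014 with the GC trend removed, 1147 without small RNA genes and all 1155 in the other alternatives), and the count was within 1.5 times with a pseudocount of 0.1, a mean of at least 5 FPKM, centred ratios and no trend. All 1155 moved the same way in all 3 experiments, so only centred ratios or removal of the GC trend could have reversed any. limma called 0 genes with no filter (4155 at an unadjusted p under 0.05), where 18972 genes were tested. Without the replicate block it called 309, 258 higher and 51 lower, all among the 1155. Leaving out an experiment gave 0 to 890 genes (0 to 599 higher, 0 to 291 lower), and 0 without experiment 1 (4474 unadjusted) or 3 (2330). The 890 came without experiment 2, where limma's smallest adjusted p was 2.78e-138. Such a value is too small to rest on 2 ratios, so no count from the fit without experiment 2 is a firm guide. Without small RNA genes 2439 were called (1233 and 1206), with 1147 of 1147 kept, and with the GC trend removed 2772 (1332 and 1440), with 986 of 1014 kept. Palmitoleate against untreated gave 5 with no filter, no block or no GC trend, 5 to 32 with an experiment left out, and 0 without small RNA (718 unadjusted). Palmitoleate against palmitate gave 5 with no filter or no block, 5 to 184, and 3 with no GC trend. Both fatty acids against untreated gave 2 with no filter, 3 at 5 FPKM, 3 with no block or GC trend, 0 to 0 with an experiment left out (250 and 99 unadjusted), and 0 without small RNA (146 unadjusted). Against palmitate they gave 9 at pseudocount 0.1, 2 with no filter, 3 at 5 FPKM, 3 with no block or GC trend, 0 to 0 (3245 and 1192 unadjusted), and 615 without small RNA. The GPAT4 knockout gave 19 at pseudocount 0.1, 13 with no filter, 4 at 5 FPKM, 14 with centred ratios, 0 to 5 (2413 and 837 unadjusted), 241 without small RNA and 17 with no GC trend. The RNF213 knockdown gave 14 to 63 untreated, 26 to 147 for palmitate against untreated, 10 to 66 under palmitate and 14 to 92 for the difference of responses with an experiment left out, the highest without experiment 2, and 6 under palmitate with no block. Without small RNA these 4 counts were 0, 8, 0 and 0 (20, 332, 69 and 16 unadjusted). The lists moved by palmitate numbered 17, against 0 with an estimated correlation and 3 with fry, which tests another null hypothesis: 2 of the 17 and the aminoacyl-tRNA synthetases. The median of palmitate-raised genes in experiment 2 was 1.66 rather than 2.30 when genes were chosen at 1.5-fold, and the other 119 medians moved by less than the spread between experiments. That spread was an SD of 0.6 for raised and 0.85 for lowered genes, wider than several of the medians themselves. Small medians could therefore change sign and still count as unmoved. CPT1A ranged from -0.30 to 0.20 with an experiment left out, and was above 0 without experiment 2 (adjusted p = 0.875). Of the palmitate values of named genes, 352 kept their direction and side of the threshold, 119 lost the call and 7 gained it. Of those in the other comparisons 3658 kept their call or stayed within 1 SE, 204 moved further and 22 lost the call. Changing the filter or the trend, or leaving out an experiment or small RNA genes, cannot alter a ratio of 2 libraries. For genes not called, such values counted as kept in advance, so the 3658 say little about stability. The cause of the shifts among named genes was not tested. The planned comparisons with the untreated GPAT4 knockout were not run, and depth limits cannot be given without read counts.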

Other observations

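In this part, the matched test restricted to palmitate-called genes and the control between wild-type experiments were chosen after the result was seen, as were the genes named for being present in 1 library.

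Further gene groups were tested with palmitate in wild type. Of 29 glycerolipid and phospholipid synthesis genes 2 rose, AGPAT9, which encodes the acyltransferase GPAT3, by 3.11 ± 0.41 and the phosphatidate phosphatase gene LPIN1 by 1.03, and of 12 lipid droplet genes 2 rose, PLIN2 and G0S2 (3.39). Of 18 fatty acid oxidation and PPAR targets 2 rose, ACAA2 by 1.64 and ACSL1 by 1.20, and of 20 aminoacyl-tRNA synthetases 7 rose, WARS by 2.09 and GARS by 1.45 among them. Of 11 interferon-stimulated genes 2 rose, IFI27 by 0.89 and IFIT3 by 0.88. Camera gave these 5 lists adjusted p values of 0.317, 0.698, 0.0762, 0.0544 and 0.242. In the glycolysis and hypoxia list VEGFA rose by 2.14 while LDHA fell by 1.17 and TPI1 fell by 0.96 (adjusted p = 0.247 for the list), and of 7 megakaryocyte genes ITGB3 rose by 2.34 while NFE2 and TUBB1 fell by 2.78 and 1.74 (adjusted p = 0.453).

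Members passed in none of 5 further lists. Heat shock proteins, mostly cytosolic but with the mitochondrial HSPE1 and HSPD1 among them, had a median log2 ratio of -0.63, with HSPE1 at -1.31. The median was -0.35 for oxidative phosphorylation with CYC1 at -0.91, and -0.38 for G2/M and mitosis with MKI67 at -0.70. It was 0.22 for cytosolic ribosomal proteins and -0.15 for proteasome subunits. Camera gave the first 4 adjusted p values of 0.00119, 0.000142, 0.0324 and 0.00127, and an adjusted p = 0.538, 0.594, 0.613 and 0.561 with an estimated correlation, and gave the proteasome 0.379. Of the markers of other cell types, all 5 B cell and all 5 endothelial genes stayed under 1 FPKM in every library, as did 3 of 5 T cell, 5 of 6 monocyte, 5 of 6 fibroblast and 3 of 6 epithelial genes, where CD3D reached 39.5, LYZ 57.8, COL1A2 2.88 and KRT19 153 FPKM.

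In experiment 2, 9 genes stood at 5 FPKM or more in the GPAT4 knockout with palmitate and under 0.5 FPKM in each wild-type library, among them NGFRAP1, MAGEB16, COL14A1, SPARC and KYNU, and 3 showed the converse, C5orf58, ALDH1A1 and TUBA3C. NGFRAP1 was at or under 0.0448 FPKM in the libraries of experiments 1 and 3, whereas KYNU stood there between 4.65 and 12.6 FPKM. TUBA3C, at 11.8 FPKM in untreated wild type of experiment 2 and 0.0739 in the knockout, stood at 1.53 and 0.452 in untreated wild type of experiments 1 and 3. In the authors' own Cuffdiff tests of experiment 2, 109 genes were higher and 13 lower with palmitate in wild type at a q-value under 0.05, 11 higher and 41 lower in the knockout than in wild type under palmitate, and 9 higher and 70 lower with both fatty acids than with palmitate.

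A hypothesis for the values nearer to untreated wild type in the GPAT4 knockout with palmitate, and for the smaller palmitate ratios in the RNF213 knockdown, is that both genotypes gave one weaker response of the same shape, so that every gene list would keep its share of the wild-type response. Against lists matched on the wild-type response of the same experiment, the median of 13 of 26 lists in the GPAT4 knockout and of 9 of 26 in the RNF213 knockdown lay outside the central 95%, where the hypothesis allowed at most 3 and more than 4 would count against it. That bound was wrong, since wild-type palmitate libraries of different experiments, matched on each other, gave 6 to 9 lists. Restricted to palmitate-called genes, 4 of 11 lists lay outside in the knockout, with the integrated stress response at 1.82 against a matched 0.91 and ER chaperones at 1.17 against 0.70, and 2 of 11 in the knockdown, against 0 to 3 between wild-type experiments. In the knockout, which exceeded these wild-type counts in both forms of the test, cholesterol synthesis stood at 1.25 against a matched 0.22 and fatty acid synthesis at 0.42 against 0, above the 0.92 and 0.04 of wild type with palmitate, where one weaker response needs less. For both genotypes one weaker response and a response of another shape cannot be told apart here. The counts of the knockdown were 9 of 26 and 2 of 11. Wild-type experiments matched on the same experiment lay little below, at 7 and 8 of 26 and at 0 and 1 of 11. The knockout was set against untreated wild type. A difference already present without palmitate, or one in the cell stock of experiment 2, neither measured in the values used, may therefore add to the medians of the knockout.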
